A study of Mus musculus with 8 samples.

How the data were processed

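Poly(A) RNA of 8 mouse libraries was measured by RNA sequencing. Per the labels' protocols, 1000000 OT-I cells, CD8 T cells whose receptor recognises an ovalbumin peptide, were given 24 hours before an ovalbumin-expressing skin graft, and spleens were taken on day 14. From each of 4 pools of 3 spleens, 1000 cells positive and 1000 cells negative for FcgRIIB, the inhibitory receptor for the constant region of IgG, were sorted within the CD44hi, Thy1.1+, CD8+ gate. The cDNA was amplified with the SMART-seq v4 kit and made into libraries with the NexteraXT kit. The labels' group and replicate number placed every library, and the groups hold 4 libraries each.

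The values used are RPKM (reads per kilobase of exon, scaled to library depth) per gene, per the file headers, as the authors deposited them. TopHat2, with no version, and the mouse build mm9 are named in the submitters' processing notes. How reads were assigned to genes, and whether strand was used, is not given in the sources used here. The table holds 13204 genes, and tested on its values, every gene reached 3 RPM (RPKM times exon length) in at least 4 libraries, so genes seen in fewer libraries are outside it. Of the Entrez gene IDs, 13187 matched the reference table of the assembly GRCm38, which was used for names only, and 17 did not. Symbols of 21 genes that a spreadsheet had turned into dates were restored through their IDs. No coordinates are given, because the table has none and the reference is of another build.

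RPKM values carry the depth when they are whole multiples of the value of 1 read for a gene of that length. Between 98.1% and 100% of the values per library came out whole within a tolerance of 0.1 reads. The depths recovered this way were 17950000, 16970000, 7360000 and 3060000 reads for negative replicates 1 to 4, and 16470000, 22010000, 6510000 and 5310000 reads for positive replicates 1 to 4. At the shallowest, 1 read was worth 0.327 RPM, and at the deepest 0.0454 RPM. Replicate spread, not counting error, sets the errors given, and reads from amplified cDNA of 1000 cells are not independent molecules.

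RPKM values are not counts, so the main test was limma (version 3.58.1 under R 4.3.3; lmFit, then eBayes with a trend) on log2(RPKM + 1), with the group as the only term, two-sided. Genes with at least 1 RPKM in at least 4 libraries were tested, which kept 11946 and left out 1258. P-values were adjusted over the genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Every fold change is on the log2(RPKM + 1) scale, positive minus negative, and understates the change of low genes. Gene lists, 31 in all and fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested. That gave 30 lists, over which p-values were adjusted. Camera with an estimated correlation and fry, directional, were run beside it. The sort markers were also compared by an exact permutation test over the 35 distinct splits of the libraries into 4 and 4, as were means over lists. This test takes no account of the pairs, and the 8 splits that exchange groups only within pairs cannot give a p below 0.125.

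Replicate numbers mark the same pool of spleens in both groups, as the series design text states. Deviations from the group means correlated at 0.70, 0.41, 0.56 and 0.68 within pairs 1 to 4, and 7 of 8 libraries correlated best with their own number. The fit with the replicate number as a block was fixed beforehand as a second fit and is given for the counts it moves by over 1.5 times and for named genes that were called with it alone of these 2 fits.

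The genes named were chosen by a rule fixed before the data were examined. It took the sort markers and, in each direction, the 10 called genes with the largest fold change that had the same direction in all 4 pairs and a proper gene name. From each list it took up to 4 called members by smallest p, or 1 or 2 members given as values where none was called. From lists of other cell types it also took the 2 most abundant members. Lists of dendritic cell subsets, red pulp macrophages, monocytes, basophils and mast cells, class II presentation, B cell genes that dendritic cells lack, core T cell genes and cytotoxic lymphocyte genes were written after the first results were seen, 10 in all. Genes named only from these were chosen after their values were seen. The single-gene values of 1 gene that the rule took are not reported here.

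The steps were tested on simulated data for the comparison of positive with negative cells. Each of 5 runs held 11946 genes, 200 of them changed, with a spread per gene taken from the main fit. At a 2-fold change 3.6% of changed genes were recovered, at 4-fold 52.8%, at 8-fold 84.4% and at 16-fold 93.6%. On average 3.6% of the calls were false. With no change simulated, at most 1 gene and 2 lists were called. Splits of the real libraries that mixed the groups called up to 18 lists, and the correlation estimated within lists reached 0.88. The simulation therefore does not show how often the list test calls falsely in these libraries.

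Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 RPKM, rescaling to a sum of 1000000, to median ratios or by quantiles, the replicate block, no trend, robust variance estimates, library quality weights, a log2 fold change of at least 1, and leaving out each library or pair. Added after seeing the data were voom on the recovered reads, a term for replicates 1 and 2 against 3 and 4, each of these sets alone, scaling to the core T cell genes, and the block without negative replicate 4. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.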

Results

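The data are gene expression profiles of antigen-specific CD8 T cells from mouse spleens 14 days after a skin graft carrying their antigen. Cells with FcgRIIB on their surface (4 libraries) were set against cells without it (4 libraries) from the same 4 pools of spleens. The comparison asks which genes differ between effector CD8 T cells that display this inhibitory Fc receptor and those that do not. Depth lay between 3060000 and 22010000 reads per library, and replicates 1 and 2 were deeper than replicates 3 and 4 in both groups. Rank correlations between libraries over all genes were 0.752 to 0.964. The first principal component (48.8% of the variance) parted replicates 1 and 2 from replicates 3 and 4, and the second (30.1%) parted the groups.

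FcgRIIB-positive libraries had more transcript of Fcgr2b itself and, with it, of many genes known from dendritic cells and macrophages. Bulk libraries do not show which cells held these transcripts, that of Fcgr2b included. On the RPKM + 1 scale C1qa, a complement gene of macrophages, was 7.38-fold higher, the class II invariant chain gene Cd74 9.95-fold and the dendritic cell receptor gene Clec9a 29.9-fold (n = 4 each). Genes linked to memory and naive T cells were lower, among them Id3 (3.97-fold), Slamf6 (3.91-fold) and Myb (3.71-fold). Relative to core T cell genes, a list written after the first results were seen, the memory and naive mean differed by 0.05 (exact permutation p = 0.80). A lower share of T cell RNA may therefore be enough for this list. Genes of cytotoxic function, such as those of granzyme B and perforin, did not pass the test (1 of 15 higher and 2 lower with the replicate block). Relative to core T cell genes the mean of 16 cytotoxic lymphocyte genes, also listed after the first results, was higher by 0.79. This held in 4 of 4 pairs (exact permutation p = 0.0286, and 0.125 within pairs). If only T cells held these genes, a lower share of T cell RNA alone is argued against for them. In the limma fit 362 of 11946 genes were higher and 32 were lower in positive cells. All 394 had the same direction in all 4 pairs and a log2 fold change of at least 1 in size. Both properties largely follow from the call on these same values, so they are not separate support.

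Because the pools pair the libraries, the fit with the replicate block is given beside these counts: it called 863 genes higher and 460 lower, among them all 394. Their direction could not differ, because every pool gave a library to both groups, so the block leaves each fold change as it was. Within replicates 1 and 2 alone 875 genes were higher and 142 lower, and within replicates 3 and 4 alone 273 and 11, fits of 4 libraries each that were chosen after seeing the data. The fold changes of these 2 sets correlated across genes, which are not independent replicates, with r = 0.65. Of the genes tested, 62.22% had the same sign in both sets. Rescaling to a common sum gave 223 higher and 8 lower, and the lower count was 19 after rescaling to median ratios and 60 by quantiles. The higher count fell to 178 without negative replicate 3, and the lower count to between 5 and 19 without any 1 of the libraries other than negative replicate 4.

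Fcgr2b (Entrez 14130), the gene of the sorted receptor, was at 48.5 ± 17.8 RPKM in positive and 3.65 ± 1.43 RPKM in negative libraries (SD, n = 4 each). Its log2 fold change was 3.40 (SE 0.36, limma adjusted p = 0.000441). The exact permutation p was 0.0286, the smallest that 35 splits allow, two-sided. Each positive library, at 69.9, 55.2, 39.1 and 29.6 RPKM for replicates 1 to 4, lay above each negative library, at 3.19, 4.82, 1.82 and 4.76 RPKM. Which cells held this transcript cannot be told from bulk libraries. Dendritic cell and macrophage lists were higher in the positive libraries as well (medians 3.20 and 2.89). The other sort markers did not pass in limma. Cd44, an adhesion receptor of antigen-experienced T cells, had a log2 fold change of 0.64 (SE 0.48), Thy1 of -0.07 (SE 0.76), Cd8a of -0.28 (SE 0.39) and Cd8b1 of -0.95 (SE 0.48). Cd8b1, the beta chain of the CD8 coreceptor, was lower in all 4 pairs (exact p = 0.0286), with a limma adjusted p of 0.488. Cd8a was also lower and Cd44 higher in all 4 pairs, with exact permutation p of 0.286 and 0.257. Thy1 parted the replicates more than the groups, with 8.48 to 24.4 RPKM in replicates 1 and 2 and 52.8 to 105.6 RPKM in replicates 3 and 4.

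**Figure D1:**
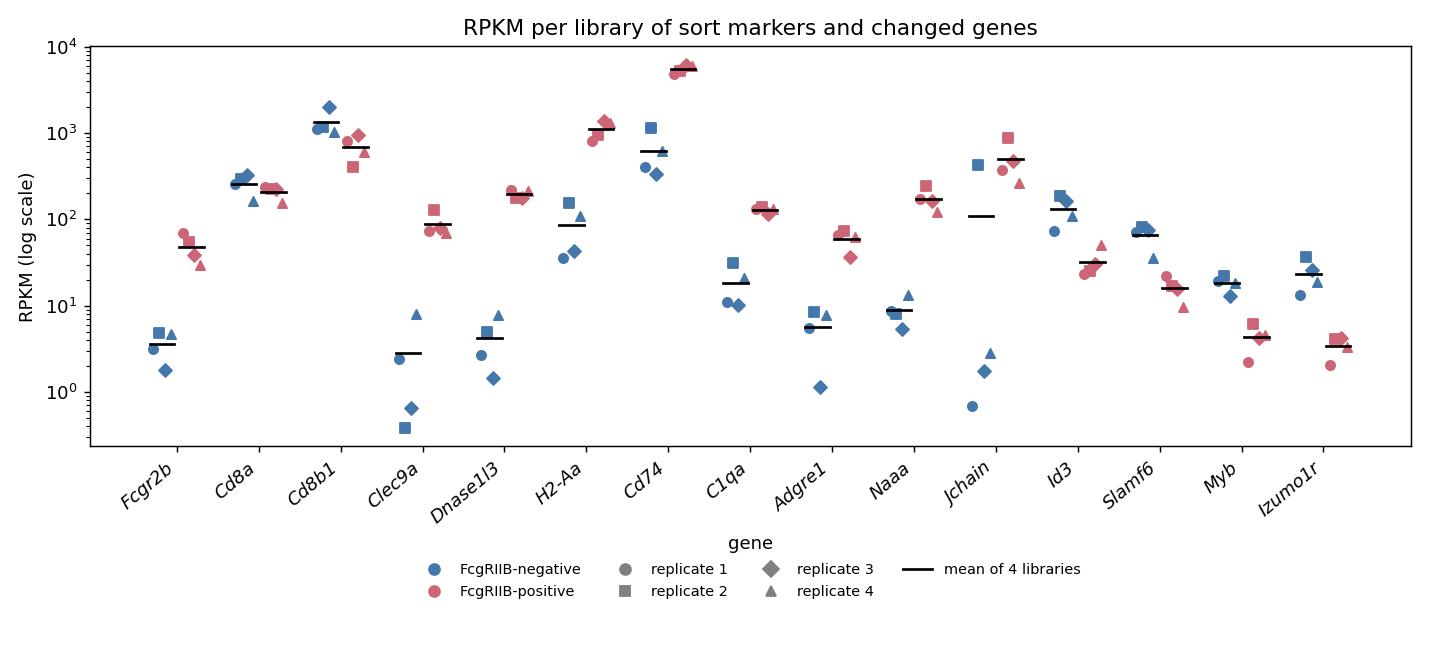
RPKM on a log axis of 15 genes in each of the 8 libraries, with colour for the group, symbol for the replicate and a bar for the mean of 4 libraries. Fcgr2b, Clec9a, Dnase1l3, H2-Aa, C1qa, Adgre1 and Naaa were higher in each positive library than in each negative one, whereas Jchain overlapped through negative replicate 2.

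Dendritic cell markers rose together, with 13 of 16 tested members higher (14 adjusted over the list alone), none lower and a median log2 fold change of 3.20. Clec9a, a receptor for dead cells on cross-presenting dendritic cells, was at 88.3 ± 27.9 against 2.85 ± 3.52 RPKM (log2 fold change 4.90, SE 0.52, limma adjusted p = 0.000441). Naaa was at 173.5 against 8.89 RPKM, Cd209a at 90.4 against 3.24 RPKM and Cadm1 at 42.6 against 2.13 RPKM, with log2 fold changes of 4.16, 4.50 and 3.77. In the same libraries the mean log2 value of 16 core T cell genes, a list written after the first results were seen, was 6.68 ± 0.43 against 7.76 ± 0.30 (SD, n = 4 each; exact permutation p = 0.0286, lower in 4 of 4 pairs). Bst2, a member that T cells also express, was at 170.0 against 193.8 RPKM and did not pass. The list was called by camera (adjusted p = 1.23e-27), but not with an estimated correlation (adjusted p = 0.0761).

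Monocyte and macrophage markers rose in the same libraries, with 16 of 23 tested members higher (22 adjusted over the list alone), none lower and a median of 2.89. C1qa, a chain of the complement protein C1q, was at 129.1 ± 9.95 against 18.4 ± 9.88 RPKM. Adgre1, the macrophage antigen F4/80, was at 59.4 against 5.73 RPKM, Cd68 at 180.5 against 22.8 RPKM and Hmox1, a haem-degrading enzyme, at 157.0 against 18.1 RPKM. Their log2 fold changes were 2.88, 3.33, 3.17 and 3.09, all called by limma. The most abundant members, Lyz2 and Tyrobp, missed the threshold at 2.19 (SE 0.66, limma adjusted p = 0.127) and 3.16 (SE 0.78, limma adjusted p = 0.0507), and were called with the replicate block (adjusted p = 0.000798 and 6.02e-06). The list passed in camera (adjusted p = 2.61e-32), with an adjusted p of 0.0889 under an estimated correlation.

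The 10 largest increases that met the naming rule were Mcpt8, Apol7c, Jchain, Dnase1l3, Clec9a, BC028528, Tlr11, Klri1, Clec4b1 and Rnase6, with log2 fold changes from 4.54 to 5.77. Dnase1l3, a secreted nuclease of dendritic cells and macrophages, was at 197.3 ± 22.2 against 4.21 ± 2.78 RPKM and had the smallest adjusted p of all genes (0.000163, limma). Mcpt8, a basophil protease, was at 16.9, 64.0, 586.6 and 547.3 RPKM in positive replicates 1 to 4 and between 0 and 7.01 RPKM in negative libraries. Without negative replicate 3 its adjusted p was 0.0548. Jchain, the joining chain of secreted antibody, was at 431.5 RPKM in negative replicate 2 and at or below 2.80 RPKM in the other negative libraries. Its limma adjusted p of 0.0487 passed with only 2 of the 8 libraries left out in turn, and reached 0.186 at the most. The other 8 stayed called whichever library was left out.

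Some Fc receptors other than Fcgr2b were higher, in the libraries in which the dendritic cell and macrophage lists were (medians 3.20 and 2.89). Of 10 tested members 5 were called higher (8 adjusted over the list alone, 8 with the replicate block), namely Fcgr2b, Fcer1a, Fcgr4, Fcgr3 and their signalling adaptor Fcer1g. Fcgr3 and Fcgr4, activating receptors of myeloid cells, were at 59.8 against 13.6 and 29.6 against 3.94 RPKM. The calls of Fcgr3 and Fcer1g ended when any 1 of 5 libraries was left out, with adjusted p up to 0.0976 and 0.156. The list's camera adjusted p, with the sorted gene Fcgr2b included, was 1.08e-09, and 0.153 with an estimated correlation. The FcgRIIB inhibitory signalling list holds phosphatases, kinases and adaptors of the receptor's signalling and its ligand gene Fgl2. Of its 12 tested members only the kinase gene Lyn was called higher (3 adjusted over the list alone, 4 with the replicate block). Its log2 fold change was 2.86 (limma adjusted p = 0.0156, and 0.0738 without negative replicate 3). The phosphatases Inpp5d and Ptpn6, named here after their values were seen, had log2 fold changes of 1.29 and -0.35 and did not pass. Inpp5d was called with the block (adjusted p = 0.00241), as were Btk at 1.63 and Fgl2 at 2.08, also named after their values were seen. The dendritic cell and macrophage lists were higher in the same libraries as this list. Camera called this list (adjusted p = 0.00598, and 0.388 with an estimated correlation), with adjusted p up to 0.122 when negative replicate 4 or positive replicate 1 was left out.

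Genes of memory and naive T cells were lower. Of 18 tested members 5 fell (10 adjusted over the list alone, 11 with the replicate block), none rose and the median log2 fold change was -0.89, with 17 of 18 members below 0. Id3, a transcriptional regulator of memory precursors, was at 32.3 ± 12.7 against 133.3 ± 52.1 RPKM (log2 fold change -1.99, SE 0.41, limma adjusted p = 0.0187). Slamf6, a surface receptor of less differentiated T cells, was at 16.1 against 66.5 RPKM, Myb at 4.31 against 18.3 RPKM and Eomes at 7.55 against 19.1 RPKM, with log2 fold changes of -1.97, -1.89 and -1.24. The fifth called member, Tcf7, named outside the rule after its value was seen, was at 37.1 against 104.8 RPKM. Camera gave an adjusted p of 3.34e-10, and 0.0889 with an estimated correlation. With single libraries left out, Myb stayed called in 8 of 8 fits, Slamf6 in 7, Id3 in 4 and Eomes in 1, with adjusted p up to 0.0239, 0.0655, 0.0897 and 0.103. After scaling each library to its core T cell genes, an alternative chosen after seeing the data, limma called no gene lower (3 at an unadjusted p under 0.05) and 1459 higher. That scaling moved the median of all genes by 1.08, to 0.97, so that the median of the memory and naive list became 0.19, of the T cell receptor list 0.22 and of the costimulatory list 0.13. Camera called all 3 as lower relative to other genes there (adjusted p = 7.84e-17, 7.37e-09 and 1.4e-05). As it compares a list with other genes, and this scaling shifts all genes of a library alike, these calls add no separate support. Id3, Slamf6 and Myb stayed below 0 there at -0.91, -0.88 and -0.81, without a call.

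T cell receptor signalling genes had a median of -0.87 over 19 tested members, of which limma called none (7 lower at an unadjusted p under 0.05, 4 lower adjusted over the list alone) and 7 lower with the replicate block. The core T cell genes, some of which are in this list, had a median of -0.98 in the same fit. Cd247, the zeta chain of the receptor complex, was at 27.4 against 67.1 RPKM and Prkcq at 21.7 against 53.5 RPKM, with blocked adjusted p of 0.000492 and 0.000526 in limma. Costimulatory receptors had a median of -0.96 over 10 members, none called by limma (4 lower at an unadjusted p under 0.05, 2 lower adjusted over the list alone) and 5 lower with the block. Cd27 and Tnfrsf9 had log2 fold changes of -1.38 and -1.22, which did not pass and were called with the block (adjusted p = 0.00115 and 0.00131). Camera called both lists (adjusted p = 9.37e-06 and 0.00215), and neither with an estimated correlation (adjusted p = 0.268 and 0.282).

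The other genes with the largest decreases were Izumo1r, Nrn1, Ephx1, Nsg2, Crtam, Rgs16 and Try5. Izumo1r, which codes for folate receptor 4, was at 3.43 ± 0.99 against 23.6 ± 9.94 RPKM (log2 fold change -2.41, SE 0.35, limma adjusted p = 0.00252), and Nrn1, a neuritin also found in T cells, at 1.46 against 11.8 RPKM. Izumo1r, Nrn1 and Nsg2 stayed called with each library left out in turn, whereas Crtam, Rgs16 and Try5 did so in 2 of 8 such fits and Ephx1 in 6. Try5 belongs to a family of near-identical trypsinogen genes, and its value is uncertain where reads are shared.

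None of 15 cytotoxic molecules passed in limma (2 lower at an unadjusted p under 0.05), also adjusted over the list alone, and the median was -0.23 (camera adjusted p = 0.728). Cst7, a protease inhibitor, and Ctsw, a cathepsin, both of cytotoxic granules, had log2 fold changes of -1.15 (SE 0.46) and -1.13 (SE 0.46), which did not pass and were called with the block (adjusted p = 0.0107 and 0.0323). Serpinb9, a granzyme inhibitor named after its value was seen, was called higher with the block (0.93, adjusted p = 0.0155). Granzyme B and perforin, named here after their values were seen, were at 276.7 ± 171.5 against 303.8 ± 171.0 RPKM (Gzmb) and 61.3 ± 55.9 against 79.7 ± 43.5 RPKM (Prf1). None of 16 effector regulators and surface markers passed in limma (1 higher and 1 lower at an unadjusted p under 0.05; median -0.15, camera adjusted p = 0.894), with Cd160 at -1.16 (blocked adjusted p = 0.00391) and Zeb2 at 1.06. Inhibitory receptors and exhaustion genes went both ways. Havcr2, which codes for TIM-3, Cd244 and Btla (the last named after its value was seen) were higher and Rgs16 and Tox lower among 18 tested (5 higher and 4 lower adjusted over the list alone, 6 and 4 with the block, camera adjusted p = 0.728). Havcr2 was at 103.0 ± 66.9 against 7.21 ± 5.48 RPKM (log2 fold change 3.62, SE 0.54) and is also known from dendritic cells, while Pdcd1, named after its value was seen, was at 8.90 against 15.4 RPKM and did not pass. Tox and Rgs16 stayed called in 2 of 8 fits with a library left out, and Cd244 in 7.

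**Figure D2:**
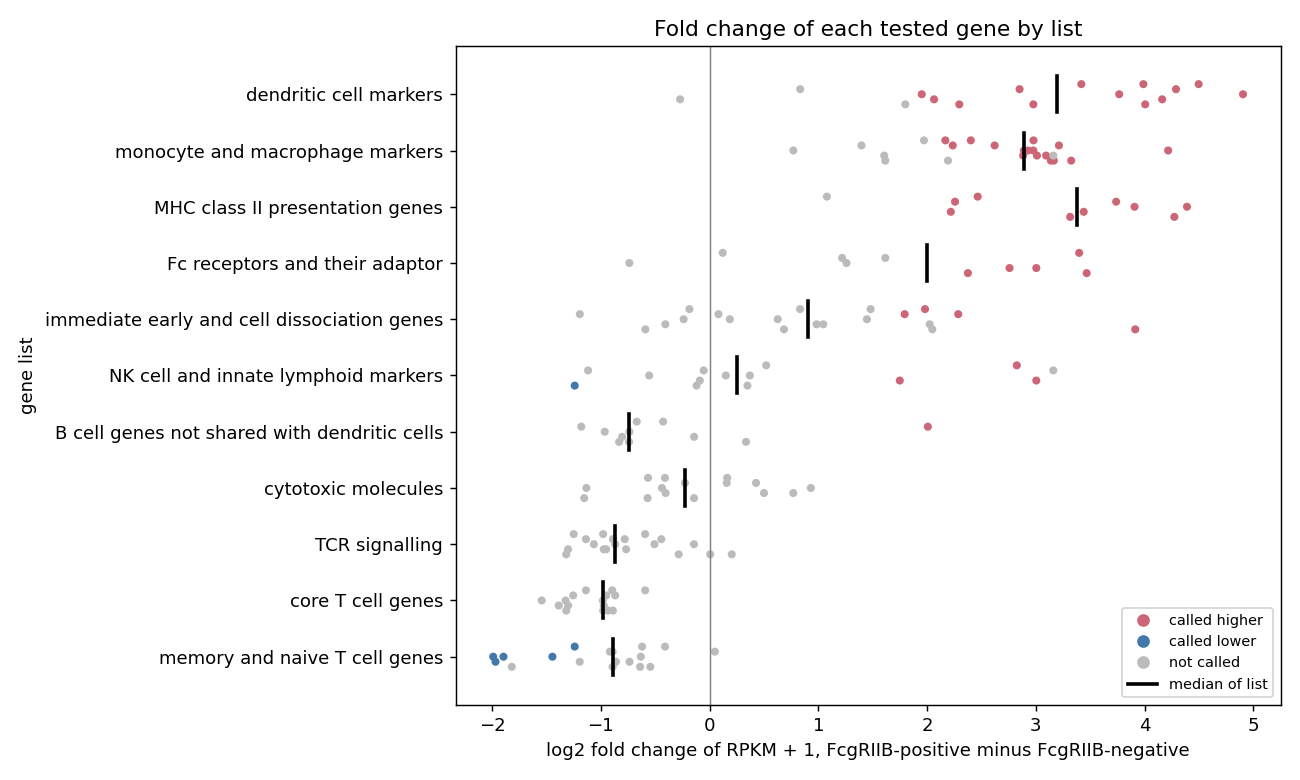
Log2 fold change of RPKM + 1 (horizontal axis) of each tested gene in 11 lists (vertical axis), with called genes coloured and a bar at the median of each list. Dendritic (median 3.20) and macrophage genes (median 2.89) lie to the right, and memory and naive genes (median -0.89) and core T cell genes (median -0.98) to the left of 0, although scaling to core T cell genes moves the memory and naive median to 0.19 and that of all genes to 0.97.

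Immediate early and cell dissociation genes were higher, with 4 of 20 called (9 higher and 1 lower adjusted over the list alone, 10 and 1 with the block) and a median of 0.91. The called members were Atf3, at 167.0 ± 41.4 against 14.9 ± 13.4 RPKM, Ier3, Fosb and Egr1, with log2 fold changes of 3.91, 2.29, 1.79 and 1.98. Egr1 stayed called in 3 of 8 fits with a library left out. The list's camera adjusted p was 1.83e-06, and 0.217 with an estimated correlation. The dendritic cell and macrophage lists were higher in the same libraries (medians 3.20 and 2.89). Among genes that promote apoptosis only Pmaip1 of 20 was higher (1 adjusted over the list alone, 1 higher and 1 lower with the block), at 193.2 against 25.3 RPKM, and its adjusted p of 0.0165 rose to 0.086 at most with a library left out. Among 14 that inhibit apoptosis only Bcl2a1a was higher (2 higher and 1 lower adjusted over the list alone, and the same counts with the block), at 280.7 against 28.2 RPKM, and its near-identical neighbours Bcl2a1b and Bcl2a1d can share its reads, so its value is uncertain. Neither list was called (camera adjusted p = 0.798 and 0.153).

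Of 9 tested cytokine genes Ccl3, a chemokine, was higher at 220.9 ± 161.4 against 22.7 ± 6.38 RPKM, and Lta was lower at 4.86 against 16.2 RPKM and called in 3 of 8 fits with a library left out (list camera adjusted p = 0.979, 1 higher and 2 lower adjusted over the list alone, 1 and 3 with the block). Among 20 chemokine receptors and homing genes Itgae was higher and Cxcr5 lower (1 higher and 2 lower adjusted over the list alone, 1 and 4 with the block, camera adjusted p = 0.29), Cxcr5 in 2 of 8 fits with a library left out. Itgae, which also marks cross-presenting dendritic cells, was at 22.7 against 4.56 RPKM and belongs with Ahr to the tissue residency list, where 2 of 14 were higher (4 higher and 1 lower adjusted over the list alone, 5 and 2 with the block, camera adjusted p = 0.0133, and 0.3 with an estimated correlation). Itgae was called in 3 and Ahr in 5 of 8 fits with a library left out, and this list lost its call without negative replicate 4 (adjusted p = 0.13). Of 21 cytokine receptors Ifngr2 alone was higher, also adjusted over the list alone, and 2 were with the block (log2 fold change 2.44, limma adjusted p = 0.0103, and 0.0548 without negative replicate 3; list camera adjusted p = 0.542).

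Markers of further cell types were mixed. Of 18 B cell markers 5 were higher, also adjusted over the list alone (5 higher and 2 lower with the block): Cd74, H2-Aa, H2-Ab1, H2-Eb1 and, named after its value was seen, Fcrla, of which the first 4 belong to class II presentation and are shared with dendritic cells. Cd74 was at 5553 ± 660 against 622 ± 363 RPKM and H2-Ab1 at 2915 ± 507 against 257.7 ± 173.6 RPKM. This list had a median of -0.08 and a mean of 0.68, and camera called it as higher (adjusted p = 0.0336), but not with the replicate block (adjusted p = 0.0661) nor with an estimated correlation (adjusted p = 0.86), and its call ended when any 1 of 5 libraries was left out (adjusted p up to 0.27). Of 9 plasma cell markers Jchain alone was called (2 adjusted over the list alone, 4 with the block, median 0.96, camera adjusted p = 0.00184, and 0.308 with an estimated correlation), with Xbp1 at 75.8 against 44.7 RPKM. None of 10 erythroid and platelet markers was called in limma (4 higher at an unadjusted p under 0.05, 3 adjusted over the list alone, 4 with the block), but all were above 0 with a median of 0.94 (camera adjusted p = 2.62e-05, and 0.153 with an estimated correlation). Haemoglobin transcripts, whose genes share reads, were at 4160 ± 3350 against 1903 ± 731 RPKM for Hba-a2 and 3627 against 1910 RPKM for Hbb-bs. For Hba-a2 positive replicates 3 and 4 were at 4765 and 8660 RPKM, and its log2 fold change was 0.05 in replicates 1 and 2 and 1.61 in replicates 3 and 4. Slc4a1, which codes for a red cell anion exchanger, had a log2 fold change of 1.92, which did not pass and was called with the block (adjusted p = 0.0012).

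Of 14 NK cell and innate lymphoid markers Klri2, Kit and Fcer1g were higher and Eomes lower (4 higher and 2 lower adjusted over the list alone, 4 and 2 with the block, camera adjusted p = 0.0776). Kit was called in 3 and Klri2 in 5 of 8 fits with a library left out. Of 12 CD4 and regulatory T cell markers Izumo1r and Cxcr5 were lower (1 higher and 3 lower adjusted over the list alone, 1 and 4 with the block). Camera called that list lower (adjusted p = 0.0441, and 0.217 with an estimated correlation), with adjusted p up to 0.122 over 6 libraries whose removal ended the call. Its median was -0.49, and that of the core T cell genes -0.98 in the same libraries. Ctla4 was at 29.8 against 76.3 RPKM and Gata3 at 11.1 against 20.7 RPKM, which did not pass and were called with the block (adjusted p = 0.000183 and 0.0424). Of 14 neutrophil markers Il1b, a cytokine that macrophages also make, was higher, also adjusted over the list alone, and 1 higher and 1 lower with the block (limma adjusted p = 0.0298, in 3 of 8 fits with a library left out). The list was not called (median -0.48, camera adjusted p = 0.893), but was called as higher without replicate 2 (median 0.441) and in replicates 3 and 4 alone (0.262). It was called as lower in replicates 1 and 2 alone (-1.07), with the block without negative replicate 4 (-0.51), and relative to other genes after scaling to core T cell genes (0.60). The gamma delta T cell list had 4 tested members, too few for the list test, and limma called none (0 at an unadjusted p under 0.05), also adjusted over the list alone. Its most abundant members were Cd163l1, at 7.12 against 8.20 RPKM, and Blk, at 3.06 against 6.93 RPKM, and Maf was at 2.84 against 1.90 RPKM.

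Growth and housekeeping lists held no called gene in this fit. None of 28 G2/M genes passed in limma (0 at an unadjusted p under 0.05), also adjusted over the list alone, and their median was 0.29, but -0.05 without negative replicate 3. Camera called this list as higher (adjusted p = 0.0441, and 0.86 with an estimated correlation), with adjusted p up to 0.882 over 4 libraries whose removal ended the call, and it was not called after rescaling to a common sum (0.0517) or by quantiles (0.055). Ube2c and Ccnb2 were at 1.10 (SE 0.63) and 1.23 (SE 0.63), with -0.02 and 0.13 in replicates 1 and 2 and 2.23 and 2.33 in replicates 3 and 4. The list's median was 0.03 and 0.42 in these sets. None of 24 G1/S genes (median -0.17, camera adjusted p = 0.54), 22 type I interferon genes (median 0.07, 0.728), 18 glycolysis genes (median -0.14, 0.893) or 30 oxidative phosphorylation genes (median -0.17, 0.479) passed in limma, also adjusted over the list alone. At an unadjusted p under 0.05 these lists held 0 genes, 1 lower, 2 higher and 0 genes, and rescaling by quantiles turned the glycolysis median to 0.008. Over 29 alternatives the type I interferon median ranged from -0.24, without positive replicate 1, to 1.155, and the list was not called. The oxidative phosphorylation list was called in opposite directions within the 2 sets of replicates, as lower in replicates 1 and 2 alone (median -0.47) and as higher in replicates 3 and 4 alone (0.268). With the block limma called Slbp (adjusted p = 0.0491), Ifit1 (0.0149), Ifit3 (0.00268), Rtp4 (0.0158) and the glucose transporter gene Slc2a1 (0.0415) lower, and Hk2 (0.000303) and Pfkfb3 (0.00157) higher, with Ifit1 and Slc2a1 named after their values were seen. Cdt1, Ndufs3 and Uqcrc1 had log2 fold changes of -0.58, -0.56 and -0.48 and did not pass in either fit. The 35 ribosomal protein genes all had fold changes below 0, with a median of -0.37, no gene at an unadjusted p under 0.05 in limma (0 with the block), and a camera adjusted p of 0.0606. Rpl3 and Rpl4 were at -0.60 (SE 0.39) and -0.62 (SE 0.41). The list was called with the replicate block (adjusted p = 0.00738) and after rescaling to a common sum (0.0105), to median ratios (0.0358) or by quantiles (0.00151). With an estimated correlation its adjusted p was 0.893, and 0.86 with the block. Their median was -0.70 in replicates 1 and 2 and 0.05 in replicates 3 and 4, so that direction did not hold in both sets of replicates. It was 0.30 with library quality weights. After scaling to core T cell genes it was 0.72 where the median of all genes was 0.97, and camera called the list as lower than other genes (adjusted p = 5.04e-06).

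In all, camera called 14 of 30 lists, 10 higher and 4 lower, and 14 with the replicate block. With an estimated correlation no list passed (smallest adjusted p = 0.0761, 6 lists at an unadjusted p under 0.05), and fry, directional, called 10. The median and the test pointed in different directions for the B cell, inhibitory receptor, apoptosis promoting, cytokine, cytokine receptor, type I interferon and sort marker lists. The sort marker list itself, with only Fcgr2b called, also adjusted over the list alone, had a camera adjusted p of 0.369.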

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

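The test of background reads was chosen only after the result was seen, whereas those of depth and of other splits of the libraries were set down before. A value was taken up here when the gap between the highest or lowest of the 4 libraries of a group and the next one made up more of the group's range than Dixon's test allows at the 95% level. Chance does this in about 1 of 20 groups. Among genes named by the rule it happened in 8 of 188 groups, against 9.4 expected by chance.

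Negative replicate 4, the shallowest library, stood apart most often. Its lower-quartile RPKM was 4.27 against 1.09 to 1.62 in the other negative libraries (gap over range 0.833), and 94.5% of its reads fell in listed genes against 99.0% to 99.7% (0.865). It was lowest of its group in Cd247 (5.31 on the log2 scale against 6.24 to 6.33, gap over range 0.912), in Slamf6 (5.19 against 6.20 to 6.39, 0.841) and in the mean of the core T cell genes (7.32 against 7.88 to 7.98, 0.849), and highest in Kit (2.16 against 0.56 to 0.83, 0.833). Positive replicate 2, the deepest library, had 16 genes listed at 0 against 0 to 1 in the other positive libraries (0.938). Its neutrophil transcripts S100a8 and S100a9 were near 0, at 0.30 and 0.19 on the log2 scale against 7.20 to 7.70 and 7.30 to 7.60 (0.932 and 0.959), and its Ccnb2 was lowest at 3.77 against 4.41 to 4.48 (0.907). Positive replicate 4 was lowest in Cd8a (7.27 against 7.81 to 7.91, 0.844). Jchain in negative replicate 2 was at 8.76 against 0.76 to 1.93 in the other negative libraries (0.854).

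Replicates 1 and 2 parted from replicates 3 and 4 in both groups, with 4917 genes called between them in limma with the group as a term, 2379 of these higher in replicates 3 and 4. Depth as the whole cause is argued against: after all libraries were thinned to 3060000 reads the number called was 95.9% of that before, (4716 genes), and 352 and 27 genes were called higher and lower in positive cells. The 2 fits shared 4560 of these genes with the same direction. Low-level background reads in replicates 3 and 4 remain a candidate explanation, since 53.0% of the genes higher there lay in the lowest tertile by mean value, against 2.4% of the genes lower there. No biological explanation was tested, since the labels give neither dates nor any difference between these pools of mice.

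The real grouping was set against all 35 ways of splitting the 8 libraries into 4 and 4. For genes higher in positive cells (362), for genes lower (32) and for both together (394), 2 of 35 splits gave as many, the real one included, so chance is not excluded by this count alone. The other was the split of replicates 1 and 2 from 3 and 4, with 2090 genes one way, 1887 the other and 3977 in all, several times the real count, which points to a structure of the samples. The remaining 33 splits called no gene in limma, with at most 2757 genes at an unadjusted p under 0.05. Of the 8 splits that part all 4 pairs, the real one called 1323 genes with the replicate block, and the other 7, which exchange the groups within some pairs, called 0, with at most 1174 at an unadjusted p under 0.05. For the count of gene lists (14), 8 of 35 splits gave as many and the highest gave 18, so chance is not excluded for the number of lists called at the preset correlation.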

How the results depend on the processing

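Tests chosen only after results were seen were voom, a term for replicates 1 and 2 against 3 and 4, each of these sets alone, scaling to core T cell genes and the replicate block without negative replicate 4. Fcgr2b kept its direction and its call in all 29 alternatives in which it was fitted, with log2 fold changes of 2.58 to 4.48. Of the other 55 called genes that were named by the rule, 22 kept their call in every alternative in which they were tested. None of the 93 other genes named by the rule passed in the opposite direction. Genes named outside the rule, after their values were seen, are not in these counts. The replicate block called 863 genes higher and 460 lower and, among lists, ended the call only of B cell markers and added only that of ribosomal proteins. Rescaling to a common sum gave 223 higher and 8 lower, median ratios 19 lower, quantiles 60 lower and no trend 19 lower. Library quality weights, whose estimation stopped short of convergence, gave 572 higher, 225 lower and 8 lists, and camera with an estimated correlation 0 lists (6 at an unadjusted p under 0.05; fry 10). With libraries or pairs left out, 178 (without negative replicate 3) to 503 (without negative replicate 4) genes were higher, 3 (without replicate 2) to 45 (without negative replicate 4) lower, and 10 to 16 lists called. The term for the 2 sets of replicates gave 742 higher and 275 lower, replicates 1 and 2 alone 875 and 142, replicates 3 and 4 alone 11 lower, scaling to core T cell genes 1459 and 0 (3 lower at an unadjusted p under 0.05 in limma), and the replicate block without negative replicate 4 1246 and 456. The neutrophil list, not called and with a median of -0.48, was called as higher without replicate 2 (median 0.441, with medians from -0.865 to 0.441 over left-out libraries and pairs) and in replicates 3 and 4 alone (0.262), as was oxidative phosphorylation there (0.268 against -0.17). In replicates 1 and 2 alone both were called as lower (-1.07 and -0.47), as was the neutrophil list with the block without negative replicate 4 (-0.51) and, relative to other genes, after scaling to core T cell genes (0.60). For all these the cause was not tested, except that fits with libraries left out hold fewer samples and the block removes the spread between pools. Over all alternatives, genes named by the rule lost a call 244 times and gained one 111 times, and lists 51 and 28 times, 3 of these in the opposite direction. Depth limits low genes most: 1 read was worth 0.327 RPM in negative replicate 4.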

Other observations

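The 10 lists described first and the tests of explanations in this part were chosen only after the results were seen, whereas the memory and naive, dendritic cell and macrophage lists were fixed beforehand. Camera's p-values for the 10 lists are adjusted over them. Lists of dendritic cell subsets were not tested against each other. Of 15 genes of the cross-presenting subset, cDC1, 13 were called higher in limma (median log2 fold change 3.82; camera adjusted p = 3.99e-31, and 0.0188 with an estimated correlation). As the list was written with these results in view, and 8 of its genes are in lists fixed beforehand, this is not independent evidence, and the same holds for the other lists here. Xcr1, a chemokine receptor of this subset, was at 81.0 ± 53.3 against 3.41 ± 0.97 RPKM (SD, n = 4 each), the transcription factor gene Irf8 at 163.6 against 14.8 RPKM, Batf3 at 78.5 against 4.02 RPKM and the Toll-like receptor gene Tlr3 at 35.3 against 0.82 RPKM. The most abundant member, Id2, which T cells also express, did not pass (848.4 against 598.3 RPKM). Of 12 genes of the other conventional subset, cDC2, 5 were higher (7 higher and 1 lower with the replicate block, median 1.75, adjusted p = 0.0296 with an estimated correlation). Of 10 plasmacytoid genes 1 was higher and 1 lower (3 and 1 with the replicate block, median 0.75, camera adjusted p = 0.0225, and 0.163 with an estimated correlation). Class II presentation rose in 9 of 10 genes (median 3.38, adjusted p = 0.0205 with an estimated correlation), with the transactivator gene Ciita at 30.2 against 1.71 RPKM and H2-Eb1 at 1475 against 87.7 RPKM.

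Red pulp macrophage genes were higher in 9 of 12 (median 2.75, adjusted p = 0.0274 with an estimated correlation), among them Spic, the regulator of that cell type, at 74.7 against 10.6 RPKM, the adhesion molecule gene Vcam1 at 112.6 against 15.6 RPKM and the most abundant member, C1qb, at 364.6 against 58.0 RPKM. Basophil and mast cell genes were higher in 3 of 8, and in 8 with the replicate block (median 1.92, 0.0296). Of 9 inflammatory monocyte genes limma called 0, with 4 higher at an unadjusted p under 0.05 and 5 with the replicate block (median 1.35, 0.0274). Of 11 B cell genes that dendritic cells lack, 1 was higher, Fcrla (1 higher and 2 lower with the block), and the median was -0.74 (0.598). Their most abundant members, Cd79a and Cd79b, were at 49.7 against 81.8 and 43.3 against 85.8 RPKM and did not pass. Cd8a, whose protein splenic cDC1 carry, lay below Cd8b1, whose protein they lack, in both groups, with a log2 difference of -1.67 ± 0.57 in positive and -2.34 ± 0.33 in negative libraries, a difference higher in positive libraries in 4 of 4 pairs that did not pass (exact permutation p = 0.0571, and 0.125, the smallest possible, within pairs). Limma called 0 of 16 core T cell genes, with 7 lower at an unadjusted p under 0.05 and 10 with the block. Their median was -0.98 (camera adjusted p = 1.49e-09, and 0.0585 with an estimated correlation). It also called 0 of 16 cytotoxic lymphocyte genes, with 0 at an unadjusted p under 0.05 and 0 with the block (median -0.35, 0.598). With the block and an estimated correlation together no list passed (lowest adjusted p = 0.0577).

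Dendritic cell and macrophage genes had fold changes above 0 in 38 of 39 tested members of their lists fixed beforehand. Of the cDC1 genes 8 and of the red pulp genes 7 were also in some list fixed beforehand, and 5 of 15 and 10 of 12 reached 5 RPKM in negative libraries too. B cells as the source of the class II rise are argued against. Class II genes rose by 3.49 more on the log2 scale than B cell genes that dendritic cells lack (4 of 4 pairs, exact permutation p = 0.0286, and 0.125 within pairs, each the smallest possible). Both lists were written after these values were seen, so the p-values are not independent evidence. Relative to core T cell genes the B cell genes differed by 0.71, higher in 4 of 4 pairs (exact permutation p = 0.286). RNA of dendritic cells and macrophages among the sorted cells is a candidate explanation, since the core T cell mean differed by -1.08 (exact permutation p = 0.0286). The sort asked for Thy1.1, CD8 and CD44, but splenic cDC1 carry the protein of Cd8a, so the CD8 gate need not remove them. This covers neither the Thy1.1 and CD44 gates nor the red pulp macrophage and basophil genes that were also higher. How RNA of dendritic cells or macrophages could have passed the gates was not tested. Expression by the T cells themselves, with the cDC1 mean higher by 3.48, cannot be told apart from RNA of such cells. Bulk libraries do not show which cell held a transcript.

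Of 18 memory and naive genes 5 were called lower in positive libraries, with a camera adjusted p of 0.0889 for the list with an estimated correlation. If only T cells held the cytotoxic lymphocyte genes, a lower share of T cell RNA alone is argued against as an account that takes them in. Their mean relative to core T cell genes was -0.41 ± 0.21 against -1.20 ± 0.28, a difference of 0.79. It was higher in 4 of 4 pairs (exact permutation p = 0.0286, and 0.125, the smallest possible, within pairs). Whether other cells held some of these transcripts was not tested. For the memory and naive genes themselves a lower share of T cell RNA may be enough, as their mean relative to the core T cell genes differed by 0.05 between groups. Less memory gene expression within the T cells cannot be told apart from none, because that difference had an exact p of 0.80 with 4 against 4 libraries. Scaled to core T cell genes, Myb and Id3 were at -0.81 and -0.91 with adjusted p of 0.179 and 0.143, so a change in single genes stays open.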
